A study of Mus musculus with 6 samples.

How the data were processed

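The series measured RNA in sciatic nerves of mice at postnatal day 3 by sequencing. It holds 6 libraries, 3 from wild-type (WT) mice and 3 from mice with a Cnp-driven Cre recombinase and the Actl6a mutation, called Actl6a conditional knockout (cKO) here. Groups and replicate numbers came from the sample titles. Per the labels' protocols, about 150 ng of total RNA entered each library. The labels do not say whether a library came from 1 animal or from several pooled. Xist and the Y-linked Kdm5d were both present in each of the 6 libraries, which argues against 1 animal per library. The p-values measure the spread between these libraries, part of which may be technical.

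The values are counts of fragments per gene, which the authors deposited as 1 table with no normalization. Per the file headers, counting used featureCounts 1.6.1 on exons of the Ensembl GRCm38 release 95 gene models, with both ends of a pair aligned, a minimum mapping quality of 20 and no use of strand. The submitters' processing notes also name Subread 2.0 and DESeq2 1.3 and the builds mm10 and GRCm38; the settings of the aligner are not given in the sources used here. Because strand was not used, reads of a gene and of an antisense partner cannot be told apart, and a read that fits near-identical copies can be lost or split by the mapping quality limit. The same table carries the exonic length of each gene in bases, per the file headers.

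The table has 54838 rows, all with a gene identifier, so 0 rows were left out of the library sizes. Symbols came from GENCODE M21 (Ensembl release 96, the same GRCm38 build, 1 release after the one counted): 54809 identifiers matched and 29 did not. Coordinates are those of the deposited table. The 37 genes of the mitochondrial chromosome had 0 counts in every library, so the list of mitochondrially encoded genes could not be tested. Total counts ran from 31404107 to 36760296 per library. Every pair of libraries within a group differed by more than sampling noise (chi-square per degree of freedom over genes, 8.98 to 16.3 between WT libraries and 31.8 to 345.8 between cKO libraries). Each counted as 1 replicate, although this comparison cannot tell separate animals from separate preparations of the same RNA.

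Testing used edgeR 4.0.16 in R 4.3.3: the low-count filter filterByExpr (minimum count of 10) by group, TMM factors, robust dispersions and the quasi-likelihood F test, 2-sided, with 4 residual degrees of freedom. All p-values called adjusted are Benjamini-Hochberg adjusted over the 18775 genes tested, and a gene was called below 0.05. Standard errors and 95% intervals of log2 fold changes were derived from the quasi-likelihood statistic. Expression levels are TMM-normalised CPM (counts scaled to the size of each library), computed here from the deposited counts. On 10 simulated sets of 18775 genes with 200 changed and a smooth dispersion trend, the test recovered 98.2% of 4-fold, 46.1% of 2-fold and 6.12% of 1.5-fold changes, and 4.86% of its calls were false. With the gene-by-gene dispersions estimated from these libraries, it recovered 90.6%, 43.9% and 4.18%, and 12.5% of its calls were false, above the nominal rate. In these simulations changes under 2-fold were therefore mostly missed, and the false share of the calls could exceed the threshold. They changed 200 genes, whereas 3534 were called in the data. The shares recovered and false therefore do not carry over to the data as values, and the shares there are not known.

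Before the data were examined, 31 gene lists, the design, the alternatives and the rule for named genes were fixed. Each list with at least 3 tested genes (30 lists) was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry beside it. Fry tests whether the members of a list move, on balance, one way and does not set them against other genes, and its p is given beside a list where its call differs from that of camera. A list's value is the median log2 fold change of its tested members. Named genes were Actl6a and Cnp; the 10 called genes with the largest fold change each way among those with an average log2 CPM of at least 1, a gene name, and no overlap of the groups' values; up to 4 members with the smallest p of each main list; and up to 2 of each other list. This gave 93 genes, some of which are not reported here. Other genes named from the fixed lists were chosen after their values were seen: Pmp22, Mbp, Prx, Mag, Pmp2, Cadm4, Pou3f1, Sox10, Nfatc4, Fa2h, Ugt8a, Pax3, Jun, Sox2, Notch1, Pcna, Cdkn1a, Mdm2, Mcpt4, Tpsb2, Col1a1, Col1a2, Dcn, Sorbs2, Hoxb5 and Hoxb6. Sox1, Gm11351, Klk9, Prss56, Gm5640 and Gm13394 lie outside the lists and come from a set that was itself chosen after its values were seen. Acat3, Gapdh and Hbb-bs are named only for the words they share. Named genes were also checked for exons overlapping another gene and for 50-base transcript words found in another gene.

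Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, TMM without muscle, blood and fat genes, no low-count filter, a stricter filter (CPM of at least 1 in at least 3 libraries), the replicate number as a block, each library left out in turn, an adjusted p under 0.01, and a change of at least 1.5-fold. A fit with the level of skeletal muscle markers as a covariate (the muscle covariate) was added after seeing the data. Figures were drawn with matplotlib 3.10.9.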

Results

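Sciatic nerves of 3 WT and 3 Actl6a cKO libraries were compared at postnatal day 3, when Schwann cells, the glia of peripheral nerves, sort and begin to myelinate axons. Actl6a encodes BAF53a, an actin-related subunit of the BAF (SWI/SNF) chromatin remodelling complex and of the INO80 and TIP60 complexes. Cnp, the gene whose name the Cre driver carries, is active in myelinating glia. The question was which transcripts of the nerve differ between the genotypes. WT libraries held 33084003, 34681637 and 36760296 counts, and cKO libraries 31435102, 31404107 and 32674317.

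Actl6a transcript in whole nerve was 49.4 ± 3.61 CPM (SD, n = 3) in WT and 43.8 ± 3.29 CPM (SD, n = 3) in cKO nerves. Its libraries read 48.6, 53.3 and 46.2 CPM in WT and 42.4, 47.6 and 41.5 CPM in cKO. The log2 fold change was -0.17 (95% interval -0.40 to 0.05, edgeR quasi-likelihood adjusted p = 0.243), so no difference was called. The gene (ENSMUSG00000027671, GRCm38 chromosome 3, 32706298 to 32726973) was counted over all exons in a tissue where many cells lie outside the Cre lineage, and the deleted part is not given in the sources used here. The count therefore checks the genotype labels only weakly. Without cKO replicate 2 the log2 fold change was -0.24 and the adjusted p 0.0487. Cnp (ENSMUSG00000006782, chromosome 11, 100574904 to 100591729) fell 5.28-fold, from 1414 ± 39.1 to 267.6 ± 78.7 CPM (SD, n = 3 each, edgeR adjusted p = 0.00146). The labels do not say whether the driver allele replaces part of Cnp.

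Of 18775 genes tested, 1605 were higher and 1929 lower in cKO nerves. The changes of at least 2-fold numbered 631 up and 732 down. The first principal component of log2 CPM held 58.9% of the variance and separated the genotypes (WT at -41.1, -45.7 and -45.2). It also set cKO replicate 2 (87.1) apart from cKO replicates 1 and 3 (19 and 25.9), so it is not an axis of genotype alone. The second component held 26.5% and again set cKO replicate 2 apart from cKO replicates 1 and 3. In cKO replicate 2, skeletal muscle marker genes took 6.51% of all counts, against 0.399 to 0.621% in the other 5 libraries. In cKO replicate 1, erythroid marker genes took 2.29%, against 0.722 to 0.779% in the other cKO libraries and 0.271 to 0.396% in WT. Without cKO replicate 2 the counts were 3425 higher and 3398 lower. Without cKO replicate 3 they were 835 and 1166, and without WT replicate 1, 2 or 3 they were 449 and 829, 483 and 822, and 456 and 790.

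Transcripts of myelin proteins fell together. Of 21 tested, 19 fell and 0 rose, with a median log2 fold change of -2.28, and the count adjusted over the list alone was also 19. Drp2, of the periaxin complex at the outer myelin surface (chromosome X, 134404551 to 134456573), fell 4.70-fold, from 341.1 ± 26.05 to 72.5 ± 15.6 CPM (SD, n = 3 each, edgeR adjusted p = 0.000679). The claudin gene Cldn19 had a log2 fold change of -2.42 and the phosphatase gene Dusp15 -2.12, both called. Pmp22 (-2.62), Mbp (-2.28), Prx (-2.31) and Mag (-1.83) were also called. Pmp2 (0.04, adjusted p = 0.932) and Cadm4 (-0.24, adjusted p = 0.599) were not. The list passed camera (adjusted p = 1.15e-21, adjusted p = 0.343 with an estimated correlation). Markers of the Schwann lineage moved with this list: 7 of 12 fell and 0 rose (median log2 fold change -0.72, camera adjusted p = 3.61e-05, adjusted p = 0.374 with an estimated correlation). Adjusted over the list alone, 9 fell and 1 rose. Of the 7 calls, 4 held without WT replicate 1 or 3. S100b, a calcium-binding protein of Schwann cells, fell from 165.3 ± 19.1 to 31.1 ± 5.98 CPM (SD, n = 3 each), and Art3 had a log2 fold change of -1.23.

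**Figure D1:**
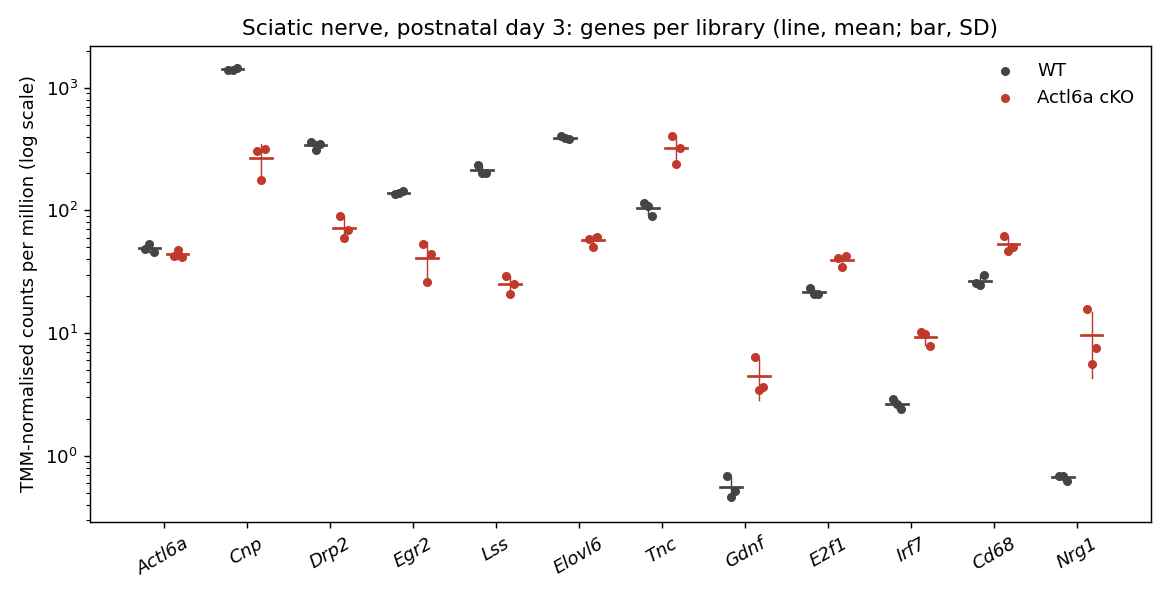
TMM-normalised CPM on a log scale (vertical axis) of 12 genes (horizontal axis) in 3 WT and 3 Actl6a cKO libraries. Points are libraries, lines means and bars SD; Actl6a lay between 41.5 and 53.3 in all 6 libraries, and Drp2 means were 341.1 in WT and 72.5 in cKO.

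Among 17 regulators of the promyelinating step, 8 fell, 1 rose and 8 were not called, with the same 8 and 1 adjusted over the list alone. Egr2 (Krox20), the transcription factor that drives myelin genes in Schwann cells, fell 3.38-fold, from 139.3 ± 3.52 to 41.2 ± 13.7 CPM (SD, n = 3 each, edgeR adjusted p = 0.00608). Tead1, a partner of YAP and TAZ, had a log2 fold change of -0.86. Chd4, of the NuRD complex, had -0.64, and Srebf2, which activates sterol synthesis genes, -0.58. Pou3f1 (-1.87) and Sox10 (-0.94) fell as well, calls that held in 1 of the 6 fits that left out a library, the one without cKO replicate 2. Nfatc4, a calcium-dependent factor, rose (0.65), a call that held in 2 of those fits. Of the 9 calls in this list, 4 held without any 1 WT library or cKO replicate 3. The list median was -0.35 (camera adjusted p = 0.00103, adjusted p = 0.374 with an estimated correlation).

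All 23 cholesterol synthesis genes fell, over all genes tested and adjusted over the list alone, with a median log2 fold change of -1.92. Lss, which closes the sterol ring (chromosome 10, 76531588 to 76557138), fell 8.50-fold, from 212.9 ± 18.2 to 25.04 ± 4.26 CPM (SD, n = 3 each, edgeR adjusted p = 0.000192). Nsdhl (-2.26), Idi1 (-2.39) and Acat2 (-2.42) followed, although 39.1% of the 50-base words of Acat2 occur in Acat3 or another gene. For Idi1 the share found in other genes was 25.3%. This list kept its call with an estimated correlation (adjusted p = 0.0259, against 7.3e-35 at the preset correlation). Of 22 genes of fatty acid and sphingolipid synthesis, 17 fell and 0 rose (19 adjusted over the list alone). Their median was -1.37 (camera adjusted p = 1.88e-19, adjusted p = 0.284 with an estimated correlation). Elovl6, an elongase of long-chain fatty acids, fell 6.87-fold, from 391.0 ± 11.6 to 56.9 ± 5.57 CPM (SD, n = 3 each). Aacs, which activates acetoacetate for lipid synthesis, had a log2 fold change of -1.99. Fa2h (-3.27) and Ugt8a (-2.65), enzymes of galactosylceramide synthesis, were called.

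Genes of immature and repair Schwann cells went both ways. Of 24 tested, 8 rose and 2 fell (9 and 3 adjusted over the list alone), with a median of 0.17 and no call for the list (camera adjusted p = 0.088). The growth factor gene Gdnf rose 8.07-fold, from 0.558 ± 0.120 to 4.51 ± 1.67 CPM (SD, n = 3 each, edgeR adjusted p = 0.00214). Tnc, an extracellular matrix glycoprotein, rose 3.07-fold, from 104.8 ± 12.3 to 322.0 ± 82.4 CPM (SD, n = 3 each). The growth cone gene Gap43 had a log2 fold change of 1.14 and Runx2 1.40. Pax3 (2.40) and Jun (0.65) rose, and Sox2 (-1.07) and Notch1 (-0.72) fell. The call of Jun was lost without WT replicate 1 or 2 and that of Sox2 without any 1 WT library or cKO replicate 3. The list was called without cKO replicate 2 (median 0.35, adjusted p = 0.00346) and without WT replicate 3 (median 0.40, adjusted p = 0.0339), with no low-count filter (0.0186) and with the muscle covariate (0.00321). Of its 10 member calls 6 held without WT replicate 1 or 2. In the list of non-myelinating Schwann cell markers, Gap43 alone of 8 was called over all genes tested, and adjusted over the list alone 1 rose and 3 fell (median -0.45, camera adjusted p = 0.17). Of these 8, 4 were called in the direction of the full set without cKO replicate 2.

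Genes of the BAF complex moved little. Of 26 tested, 2 rose, 3 fell and 21 were not called (2 and 6 adjusted over the list alone), with a median of -0.08 (camera adjusted p = 0.208). Bicra had a log2 fold change of -0.64 (edgeR adjusted p = 0.0145) and Ss18l1 -0.57, and Smarcd2 had 0.44 and Smarca2 0.33. Each of these 4 calls was lost in at least 2 of the fits that left out a library, and without WT replicate 1 all 5 calls in the list were lost. Without cKO replicate 2, 10 members were called in the direction of the full set. Of 24 genes of the INO80 and TIP60 complexes, 3 fell and 0 rose (1 adjusted over the list alone), among them Brd8 (-0.41) and Actr8 (-0.42), with a median of -0.11 (camera adjusted p = 0.208, fry adjusted p = 0.00928). All 3 calls were lost without any 1 WT library, and that of Actr8 also without cKO replicate 1 or 3. Of 20 histone methylation enzymes 4 fell, both over all genes tested and adjusted over the list alone, with a median of -0.15 (camera adjusted p = 0.0261, adjusted p = 0.374 with an estimated correlation). The H3K9 and H3K36 demethylase gene Kdm4a had -0.77 and the H3K4 methyltransferase gene Kmt2d -0.83. This list was not called without cKO replicate 2 (adjusted p = 0.0683) or with the muscle covariate (adjusted p = 0.0658), and 2 of its 4 member calls held without any 1 WT library. Without cKO replicate 2, 8 members were called in the direction of the full set.

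Of 29 cell cycle genes, 5 rose and 0 fell (5 adjusted over the list alone), with a median of 0.18 (camera adjusted p = 0.0816). They were E2f1, Pcna and the replication licensing genes Mcm3, Mcm4 and Mcm6. E2f1, a transcription factor of S phase entry, rose 1.84-fold, from 21.5 ± 1.49 to 39.6 ± 4.09 CPM (SD, n = 3 each, edgeR adjusted p = 0.00335). Log2 fold changes were 0.52 for Mcm6, 0.51 for Mcm3 and 0.36 for Mcm4, and these 3 calls and that of Pcna (0.45) were lost without any 1 WT library or without cKO replicate 3. The list was called without cKO replicate 1 or 2 or WT replicate 1 or 2 (adjusted p 0.0372 to 0.0462) and with the muscle covariate (0.0193), and not without WT replicate 3 (0.424) or cKO replicate 3 (0.486). Without cKO replicate 2, 12 of its members were called in the direction of the full set. Among 21 p53 targets and cell cycle inhibitors, 4 rose and 1 fell (4 and 1 adjusted over the list alone), with a median of 0.46 (camera adjusted p = 0.0223, adjusted p = 0.501 with an estimated correlation). Pmaip1 (Noxa), a pro-apoptotic gene, rose (2.32), and Cdkn1b (p27), an inhibitor of cyclin-dependent kinases, fell from 272.1 ± 19.0 to 91.1 ± 15.1 CPM (SD, n = 3 each). Of the 21, 16 were not called, among them Cdkn1a (-0.40, edgeR adjusted p = 0.234) and Mdm2 (0.21, edgeR adjusted p = 0.276). That list was not called without cKO replicate 1 (adjusted p = 0.0837) or WT replicate 2 (0.0529). Of its 5 member calls 2 held without any 1 WT library, and 13 members were called in the direction of the full set without cKO replicate 2.

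All 15 interferon response genes rose, over all genes tested and adjusted over the list alone, with a median of 1.65 (camera adjusted p = 2.77e-13, adjusted p = 0.343 with an estimated correlation). Irf7, a regulator of interferon genes, rose 3.48-fold, from 2.66 ± 0.255 to 9.27 ± 1.23 CPM (SD, n = 3 each, edgeR adjusted p = 0.00119), and Rtp4 had a log2 fold change of 1.58. Without 1 WT library 10 or 11 of the 15 calls held. Of 13 macrophage markers 10 rose and 0 fell (12 adjusted over the list alone), with a median of 0.87 (camera adjusted p = 6.12e-07, adjusted p = 0.422 with an estimated correlation). The lysosomal gene Cd68 had 0.99 and the mannose receptor gene Mrc1 0.77, calls that held in all 6 fits that left out a library. Of the 10 macrophage calls, 3 held without WT replicate 1, 4 without WT replicate 2 or 3 and 6 without cKO replicate 3. Of 9 markers of mast cells, T cells and neutrophils 4 rose and 0 fell (7 adjusted over the list alone, median 0.90, camera adjusted p = 0.00171, adjusted p = 0.343 with an estimated correlation). The 4, Cpa3, Cma1, Mcpt4 and Tpsb2, are mast cell protease genes, and all 4 calls were lost without WT replicate 1 or 3, and 3 of them without WT replicate 2. Erythroid genes moved with these groups: 4 of 7 rose (7 adjusted over the list alone, median 1.91, camera adjusted p = 0.000603, adjusted p = 0.45 with an estimated correlation, fry adjusted p = 0.0774). All 4 calls were lost without cKO replicate 2 or any 1 WT library. Hbb-bt (2.12) shares 58.3% of its words with Hbb-bs, which leaves its count uncertain. Without cKO replicate 1 the erythroid median was 1.21 and the log2 fold change of Hbb-bt 1.42.

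**Figure D2:**
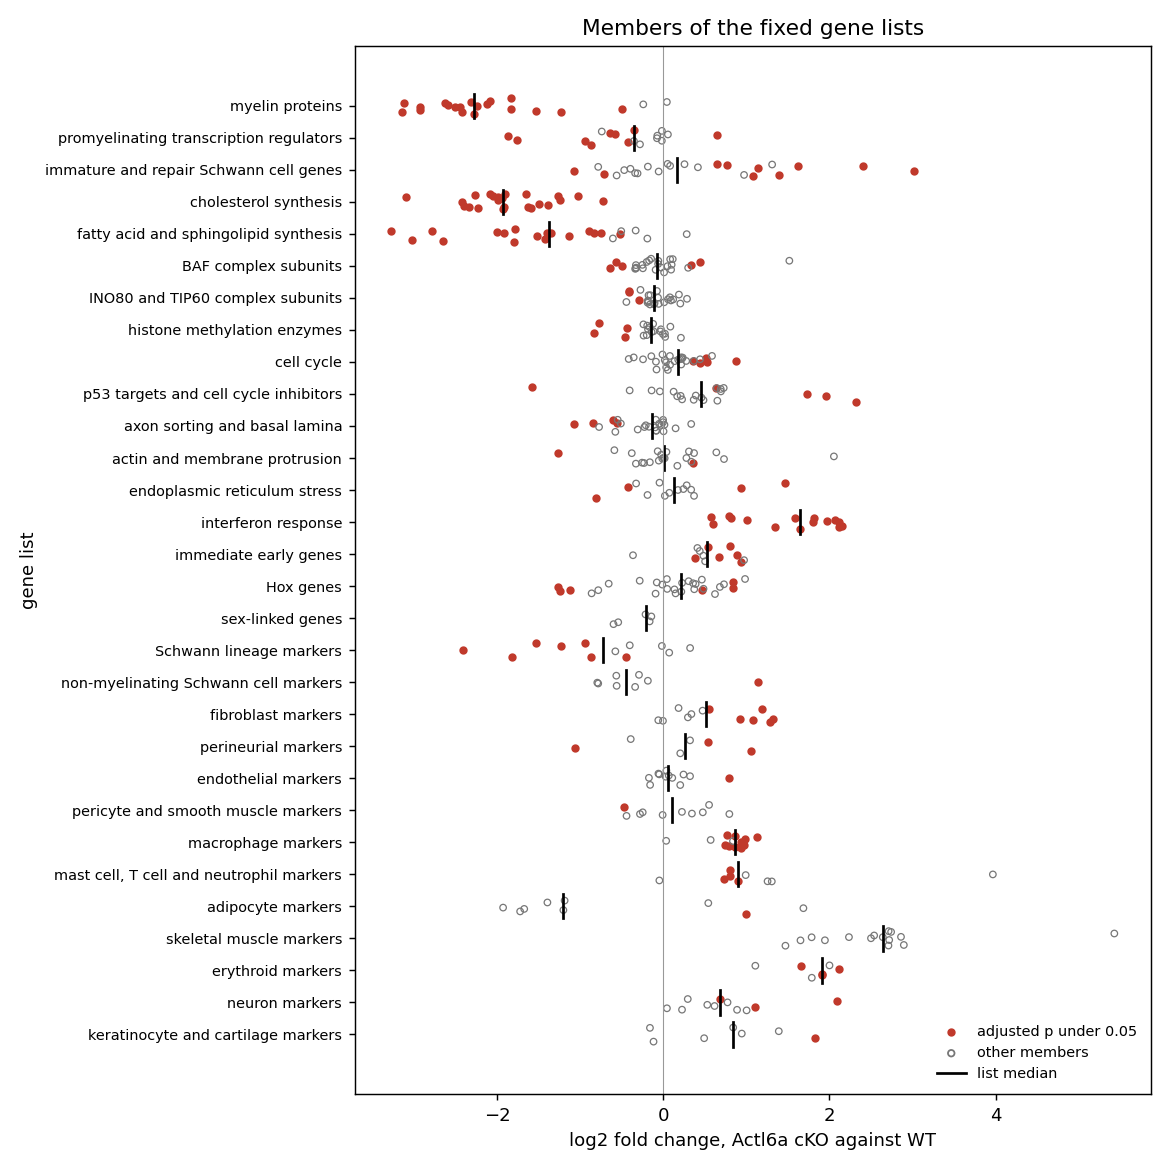
Log2 fold change of Actl6a cKO against WT (horizontal axis) for each tested member of the 30 tested gene lists (vertical axis). Filled points passed an adjusted p of 0.05, open points did not, and black lines are list medians, which ran from -2.28 for myelin proteins to 2.64 for skeletal muscle markers.

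Of 12 fibroblast markers 6 rose and 0 fell (6 adjusted over the list alone, median 0.52, camera adjusted p = 0.000153, adjusted p = 0.374 with an estimated correlation). Among them were Dpp4 (1.32) and Clec3b (1.08). The other 6 were not called, from -0.06 for Col1a2 and -0.002 for Col1a1 to 0.47 for Dcn, so the list did not rise as a whole. Of 6 perineurial markers 2 rose and 1 fell (2 and 2 adjusted over the list alone, median 0.26, camera adjusted p = 0.769), with Lypd2 at 1.06 and Ntn4 at 0.54. All 3 calls were lost without any 1 WT library or without cKO replicate 3, and all 6 markers were called in the direction of the full set without cKO replicate 2. The perineurial median ranged from 0.09 to 0.44 in the fits that left out a library. The angiopoietin receptor gene Tek (0.80) was the 1 of 12 endothelial markers that was called, also adjusted over the list alone (median 0.05, camera adjusted p = 0.414). Esam had 0.24 (adjusted p = 0.0965). Among 10 pericyte and smooth muscle markers Pdgfrb fell (-0.47, call lost without WT replicate 1 or 3) and 0 rose (2 and 1 adjusted over the list alone, median 0.11, camera adjusted p = 0.794). Kcnj8, at 0.48, was not called, but was with DESeq2 (adjusted p = 0.0196), with no low-count filter (0.036) and without cKO replicate 2 (0.000143), where 4 of these markers were called in the direction of the full set. Of 11 neuron markers 3 rose and 0 fell (4 adjusted over the list alone, median 0.68, camera adjusted p = 0.0059, adjusted p = 0.569 with an estimated correlation, fry adjusted p = 0.131), with Tubb3, a neuronal tubulin, at 2.09 and Isl1 at 1.10. All 3 calls were lost without cKO replicate 3 or any 1 WT library, and that of Isl1 also without cKO replicate 1, while 8 neuron markers were called in the direction of the full set without cKO replicate 2.

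All 15 skeletal muscle markers missed the threshold, among them Myh4 (5.43) and Myog (2.72), and 0 passed adjusted over the list alone. Their median was 2.64 (camera adjusted p = 0.0322, adjusted p = 0.72 with an estimated correlation, fry adjusted p = 0.412) and 0.42 without cKO replicate 2 (adjusted p = 0.43). The list was also not called without WT replicate 2 (adjusted p = 0.0603) or with the muscle covariate (0.695). DESeq2 called Myh4 (adjusted p = 0.00413) on all 6 libraries, but its edgeR log2 fold change was 1.94 without cKO replicate 2 (adjusted p = 0.277). In the fit without cKO replicate 2, 3 of the markers were called, among them Myog (0.57, adjusted p = 0.0102). Of 9 adipocyte markers, Fabp4 rose (0.996, also adjusted over the list alone), a call lost in 5 of the 6 fits that left out a library, and Cfd had -1.92 (adjusted p = 0.154), with a list median of -1.20 and camera adjusted p = 0.642. Without WT replicate 3 the median was -0.10 and Cfd had -0.82. Of 7 keratinocyte and cartilage markers Krt1 was called (1.83), lost without any 1 WT library or cKO replicate 3. Its level was low, at 0.403 ± 0.151 CPM in WT and 1.45 ± 0.778 CPM in cKO (SD, n = 3 each). Adjusted over the list alone, 0 of these markers were called. The median was 0.84 (camera adjusted p = 0.299; without cKO replicate 1, 1.22 and 0.0196, with 3 markers called; without cKO replicate 3, 0.06 and 0.942).

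**Figure D3:**
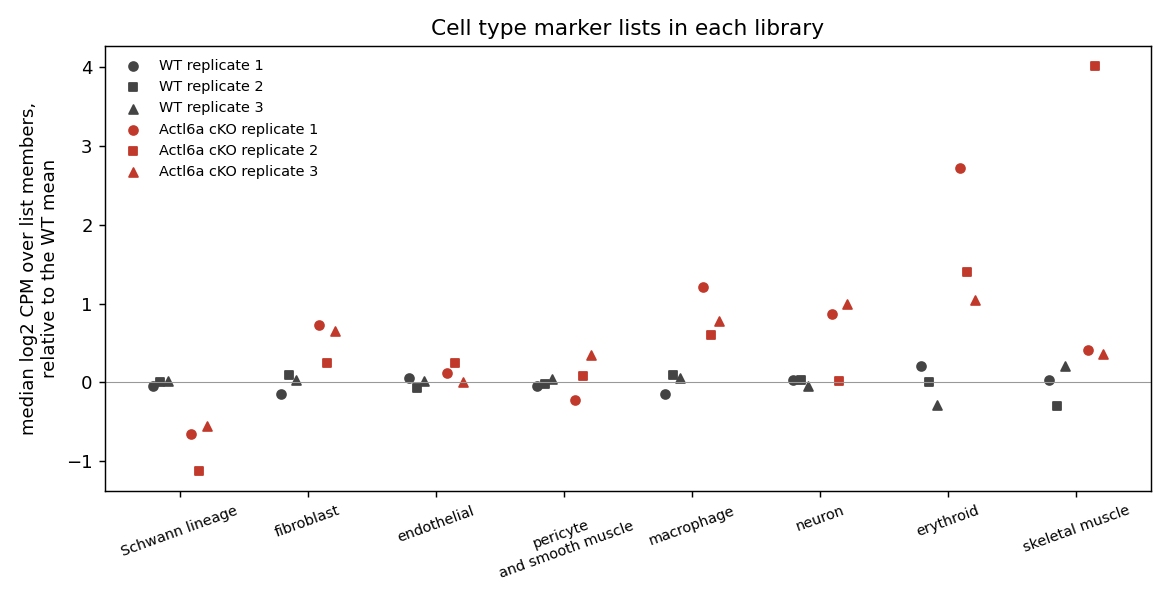
Median log2 CPM over the members of 8 cell type marker lists (horizontal axis), relative to the mean of the WT libraries (vertical axis), in each of 3 WT and 3 Actl6a cKO libraries. Skeletal muscle markers stood at 4.01 in cKO replicate 2 and at 0.42 and 0.36 in cKO replicates 1 and 3.

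Among the largest rises was Prkg2, a cGMP-dependent protein kinase (chromosome 5, 98929773 to 99037351). It rose 36.0-fold, from 1.97 ± 0.314 to 71.1 ± 51.8 CPM (SD, n = 3 each, edgeR adjusted p = 0.00656), and its log2 fold change moved from 5.17 to 4.39 without cKO replicate 1. Nrg1, the growth factor that signals through ErbB receptors of Schwann cells (chromosome 8, 31814551 to 32884029), rose 14.3-fold, from 0.671 ± 0.036 to 9.60 ± 5.31 CPM (SD, n = 3 each, edgeR adjusted p = 0.00256). Tnfrsf19, a member of the TNF receptor family, had a log2 fold change of 3.77. The kallikrein genes Klk10 and Klk8 had 4.03 and 3.55, the glutamate receptor gene Grm7 3.61, and Dhrs2, Itprid1 and Btbd16 had 3.63, 3.74 and 3.35. Exons of Klk8 overlap an antisense gene over 24.8% of their length. The pseudogene Xlr3d-ps (4.79) shares 69.1% of its words with other genes, so its reads are uncertain.

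Among the named genes, the largest fall was that of Slc36a2, a proton-coupled amino acid transporter (chromosome 11, 55158470 to 55185077). It dropped 36.2-fold, from 139.7 ± 6.03 to 3.86 ± 0.470 CPM (SD, n = 3 each, edgeR adjusted p = 2.32e-05). Hepacam, a glial adhesion gene, had a log2 fold change of -4.27, and Mfsd2a, a transporter of lysophosphatidylcholine, -4.19. The orphan receptor gene Gpr37 had -3.69, the norrin gene Ndp -4.08, and Fam178b, Lrtm2 and Ddn -4.85, -3.77 and -3.74. Smco3 (-5.04) and BC049715 (-3.68) lie on opposite strands of the same locus, with 95.8% of the exon bases of Smco3 overlapped, so unstranded counts do not tell which of the pair fell.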

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

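The muscle marker covariate was chosen after seeing the data; the other alternatives were planned. Of the 93 named genes, 60 kept their direction and side of the threshold in every alternative fit that tested them (the stricter filter left out 2 and DESeq2 gave 1 no adjusted p), and cholesterol synthesis and BAF complex subunits did so among the 6 main lists. The counts of 1605 higher and 1929 lower genes stayed within 1.5 times with DESeq2, limma-voom, RLE and upper-quartile factors, TMM without muscle, blood and fat genes, and both other low-count filters. The stricter threshold and the 1.5-fold limit were applied to the counts alone. These were 466 and 788 at an adjusted p under 0.01, the lower genes numbered 1255 at 1.5-fold or more, and with the muscle covariate there were 3071 and 3130. Leaving out a library gave 449 to 3425 higher and 790 to 3398 lower genes. The extremes lay without WT replicate 1 or 3 and without cKO replicate 2. Same-numbered libraries did not deviate together (correlations -0.223, -0.231 and -0.08 across genes). This cannot decide whether the numbers pair them. Groups are small, and each deviation was taken from the mean of its own group, which by itself makes correlations within a group negative. Between WT libraries they were -0.56, -0.552 and -0.382. For cKO replicate 2 against cKO replicates 1 and 3 they were -0.839 and -0.772, and between cKO replicates 1 and 3 the value was 0.302. With the replicate block 744 and 1108 genes were called, from 2 residual degrees of freedom, and the histone methylation list had a camera adjusted p of 0.053. Of the 93 named genes 16 were no longer called in that fit and 77 kept their side of the threshold.

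With an estimated correlation camera no longer called myelin proteins (-2.28) or promyelinating regulators (-0.352). It also dropped a list whose estimated correlation was near the preset 0.01, histone methylation enzymes (0.0301, camera adjusted p 0.0261 to 0.374). The immature and repair list became called with no low-count filter (0.321) and the muscle covariate (0.347), and ranged from 0.063 to 0.396 without a library. The cell cycle list became called with the muscle covariate (0.207) and ranged from 0.088 to 0.196. Actl6a ranged from -0.238 to -0.132. Values that changed sign were uncalled: Xist (-0.959 to 0.095 without a library), sex-linked genes (-0.535 to 0.097), and actin and membrane protrusion (-0.046 to 0.084, -0.00122 with TMM without muscle, blood and fat genes and -0.0127 with no low-count filter). Fry gave the same call as camera for 26 lists, ended 3 (erythroid, neuron and skeletal muscle markers) and added 1 (INO80 and TIP60 subunits). Calls of Smarca2, Mcm4, Vasp, Ntn4, Hbb-bt and Tubb3 were lost with no low-count filter, of Smarca2 with upper-quartile factors, of Krt1 with limma-voom, and of Fabp4 and Hbb-bt with the muscle covariate. The cause of these shifts was not tested. Depth limits genes under about 1 CPM, where a library holds few counts.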

Other observations

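Of 24 genes of axon sorting and the basal lamina, 4 fell and 0 rose (9 adjusted over the list alone, median log2 fold change -0.13, camera adjusted p = 0.0104, adjusted p = 0.569 with an estimated correlation, adjusted p = 0.081 with the muscle covariate). Of the 4 calls 1 held without WT replicate 1, and 2 without WT replicate 2 or 3 or cKO replicate 3, while 11 members were called in the direction of the full set without cKO replicate 2. Erbb2, the neuregulin co-receptor, had -0.84 and Adgrg6 (Gpr126), a receptor needed for Schwann cell myelination, -1.07, and the call of Adgrg6 was lost without WT replicate 1. Of 12 immediate early genes 6 rose and 0 fell (10 adjusted over the list alone, median 0.53, camera adjusted p = 0.00103, adjusted p = 0.374 with an estimated correlation). Fos had 0.88 and Btg2 0.81, and both calls were lost without WT replicate 2 or 3 and that of Btg2 also without WT replicate 1. Of the 6 calls 0 held without WT replicate 2 or 3, 1 without WT replicate 1 and 3 without cKO replicate 3. Of 14 genes of endoplasmic reticulum stress 2 rose and 2 fell (3 and 3 adjusted over the list alone, median 0.13, camera adjusted p = 0.572). Asns, asparagine synthetase, had 1.47 and Atf3 0.93, and all 4 calls were lost without any 1 WT library. Of 23 genes of actin and membrane protrusion 1 rose and 1 fell (0 and 1 adjusted over the list alone, median 0.01, camera adjusted p = 0.964), Vasp at 0.36 and Wasf1 at -1.26, and the call of Vasp was lost without any 1 WT library or cKO replicate 3. Of these 23 genes, 10 were called in the direction of the full set without cKO replicate 2.

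Of 29 Hox genes 3 rose and 3 fell (3 and 3 adjusted over the list alone, median 0.22, camera adjusted p = 0.735). The list median ranged from 0.08 to 0.28 in the fits that left out a library. Hoxa10 rose (0.84), and Hoxb5 (-1.24), Hoxb6 (-1.12) and Hoxb7 (-1.26) fell in each of the 6 fits that left out a library. Hoxb7 lies at 96286623 to 96290162 on chromosome 11, within 10 Mb of Cnp (100574904 to 100591729). So do Erbb2 (98412470 to 98437716) and Smarcd2 (106263179 to 106272972), whose changes are given above. Whether DNA of another strain around Cnp plays a part in the changes of these genes was not tested. Of 5 sex-linked genes 0 were called, also adjusted over the list alone (median -0.21, camera adjusted p = 0.642). Xist (251.6 to 1011 CPM in WT, 205.4 to 518.0 CPM in cKO) and the Y-linked Kdm5d (9.54 to 29.6 and 7.97 to 20.8 CPM) were both present in each of the 6 libraries. RNA of a single sex would lack Xist or Kdm5d, so these values argue against libraries from single animals.

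In the paragraphs that follow, all tests were chosen after the result was seen except the count of splits and the search for shared transcript words over the whole set of genes. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 3534 genes, the highest of the other splits called 0, and 1 split, the real one, gave as many. Every other split mixed the genotypes within its groups, which adds genotype differences to the spread. Their counts are therefore no reference for libraries without a difference.

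The fall of myelin protein transcripts was set against a lower share of Schwann cells. That would lower all Schwann cell markers alike, but the myelin median lay below that of 11 Schwann lineage markers outside the myelin list in each cKO library, by at least 1.37 log2 units (-1.37, -1.93 and -1.64, against -0.05 to 0.06 in WT). Other cell types moved apart, with medians of 0.05 for endothelial, 0.52 for fibroblast (6 of 12 called) and 0.87 for macrophage markers. Muscle RNA in cKO replicate 2 does not account for it either, since the median was -2.08 without that library. The 11 lineage markers were themselves spread, from -2.41 for S100b to 0.32 for Sorbs2, so their median is only a rough gauge. The gap speaks only to a loss of all Schwann cells alike, not to a loss of a subset of them. A smaller Schwann cell share as part of the fall stays open, and so does an effect of the genotype, which was not tested apart from it.

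The rise of interferon response genes was set against a larger share of macrophages. In each cKO library the interferon median exceeded that of the macrophage markers, by at least 0.625 log2 units (0.625, 0.885 and 0.697, against -0.09 to 0.06 in WT), so a larger share alone does not account for it. Blood in cKO replicate 1, the library with most erythroid counts, does not either, since the median was 1.52 without it. The erythroid lists of cKO replicates 2 and 3 were also above WT (1.40 and 1.04), so blood in all 3 remains open. An effect of the genotype also stays open, and the cell type in which these genes rose was not tested.

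A set chosen after its values were seen held 15 genes under 0.3 CPM in every WT library and above 1 CPM in every cKO library, and 9 genes the other way round. Of the 9, Gm13394 shares 94.7% of its 50-base words with Gapdh and Smco3 93.0% with BC049715, so the reads of these are uncertain. Among the 15 were the neural transcription factor gene Sox1 (0 to 0.029 CPM in WT, 1.26 to 2.40 in cKO), the noncoding RNA Gm11351 (0.027 to 0.090 and 16.3 to 38.1), Klk9 and Prss56. Skeletal muscle RNA in cKO replicate 2 alone could not give this set, because its choice required every cKO library above 1 CPM. The data therefore add no test of that source. Within the set, that library was the lowest of the cKO libraries for 13 of the 15 and the highest for 0. DNA of another strain around the targeted and driver genes does not account for the set, as 0 lie within 10 Mb of Actl6a or Cnp (2.26% of tested genes do). Reads from near-identical copies do not account for the set, as 2 of the 15 have most of their 50-base words in another gene, but for these 2, Gm5640 (92.2%) and Xlr3d-ps (69.1%), the source of the reads cannot be told apart. For the others an effect of the genotype stays open, and no mechanism was tested.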
